A study of Homo sapiens with 18 samples.

How the data were processed

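Messenger RNA of NCI-H1693, an established human non-small cell lung cancer line that the labels call SMARCA4-deficient, was measured by sequencing after 6, 48 or 72 h in 50 nM PRT3789 or in DMSO, with 3 libraries in each of the 6 groups. Per the labels, RNA came from flash-frozen pellets, was enriched with oligo(dT), made into stranded libraries and read as 150 bp pairs. The authors processed the reads with the nf-core/rnaseq pipeline 3.17.0 (Trim Galore for trimming, STAR for alignment to GRCh38 with annotation release 110, RSEM for quantification); versions of the single tools are not stated. The deposited table holds expected counts for 43236 gene symbols in 18 columns. Its values were already whole numbers, so that unrounded counts could not be compared. Of the symbols, 16043 had a count of 0 in every library.

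Library totals ran from 23154484 to 31094797 counts. The reads carry no molecular identifiers, so depth limits only counting error and does not measure the spread between cultures. Groups were taken from the labels. The labels do not say whether the replicates of a group were separate cultures. The spread between libraries that each p rests on may thus be technical. That spread was pooled over all times, while the 6 h libraries differed more than the later ones, so a p at 6 h can be too small. Replicate numbers were not used as pairs: over the 9 pairs of libraries that shared a number and a time, the correlation of their deviations from the group means, taken across genes, ran from -0.237 to 0.338.

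Genes were kept by filterByExpr with the 6 groups, which left 16291 genes; the others held at most 0.048% of the counts of any library. Counts were scaled by the trimmed mean of M values (TMM) and tested in edgeR 4.0.16 (R 4.3.3) with robust two-sided quasi-likelihood F tests in one model of all 18 libraries, with one mean per group. Contrasts were PRT3789 against DMSO at each time, the change of that effect between neighbouring times (an interaction test), and DMSO between neighbouring times. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, taken over all tested genes of a contrast. Log2 fold changes (log2FC) are edgeR estimates with their standard error (SE). Levels are in edgeR CPM, the counts of a gene over the TMM-scaled library total, given as mean ± SD over 3 libraries. Log2 CPM used a prior count of 2.

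The 36 gene lists are SWI/SNF subunits, other chromatin remodellers, polycomb repressive complexes, the VHL ubiquitin ligase, S phase, G2/M phase, homologous recombination and Fanconi anaemia, cell cycle inhibitors and p53 targets, apoptosis regulators, MYC and its targets, AP-1 factors, immediate early and heat shock genes, YAP/TEAD targets, MAPK feedback, epithelial junctions and keratins, mesenchymal genes, collagens and matrix, integrins and cell adhesion, interferon-stimulated genes, antigen presentation, NF-kB and cytokines, TGF-beta and BMP targets, Wnt and Notch targets, cholesterol synthesis, fatty acid and lipid metabolism, hypoxia and glycolysis, the unfolded protein and integrated stress response, NRF2 targets, mitochondrially encoded genes, oxidative phosphorylation, ribosomal proteins, the proteasome, lung epithelial lineages, neuroendocrine and neuronal genes, blood cell markers, and endothelial and fibroblast markers. All 1092 symbols of the lists were in the table. Each list was tested against the other genes with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over 108 tests (36 lists at 3 times), and again with a correlation estimated per list. Some other groupings of the same libraries gave as many list calls at the preset correlation as the real groups, as given below. Changes of list effects between times were adjusted over 72 tests.

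Named genes are SMARCA2, SMARCA4, KRT80 and PLAU, the 4 members with the smallest p of each list, and called genes with the largest changes. The last were 10 rises and 10 falls for each treatment comparison, 5 per direction for the change of effect and 3 for DMSO over time. They needed a mean of at least 5 CPM over the libraries and an official symbol that was no readthrough name. Except for the change of effect, the CPM of the compared groups also had to lie apart without overlap. Separation of the libraries was thus imposed on these genes. Members that the rule took from a list are counted with their list, and only some are named in the text; 1 gene is not reported here by name. The contrasts, lists, naming rule, thresholds and a first set of alternatives were chosen before the data were examined. Genes outside the rule are named as chosen after their values were seen.

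That set of alternatives was DESeq2 1.42.0 size factors, total counts without composition factors, no filter, a filter of 1 CPM in at least 3 libraries, DESeq2, limma-voom, replicate number as a block within each time or over all groups, each library left out in turn, each time point fitted apart, an adjusted p under 0.01, a change of at least 2-fold, and the estimated correlation. Chosen after the data were seen were a fit without the genes of a repeating pattern, a fit without ribosomal RNA genes, and a fit with each library's trend against transcript length removed. That trend was a lowess curve (span 0.3) of a library's deviation in log2 CPM from the mean on the log of the canonical transcript length in GENCODE 44, and it entered edgeR as offsets. A length was found for 15005 tested genes (92.1%). The shortest quartile had at most 1896 nt and the longest at least 5049 nt.

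The steps were tested on simulated data with planted changes of 1.5-, 2- and 4-fold. Where all times had one spread, 4.37% of edgeR calls at 6 h were false. Where each time kept its own spread, 55.2% of the 6 h calls of the joint model were false, against 6.67% with the time fitted apart; the joint model gave 1.68% at 48 h and 1.73% at 72 h. Planted 4-fold changes at 6 h were found for 100% of genes and 1.5-fold changes for 65.7% in the joint model, against 95.5% and 16.4% with the time fitted apart. The search for genes raised in 3 neighbouring libraries found 18 of 20 planted genes with 1 false gene higher and 2 lower where all times had one spread, and 19 of 20 with 193 false genes higher and 235 lower where each time kept its own. Gene coordinates are on GRCh38, matched by symbol for 15962 genes. Counts were not corrected for the copies of ribosomal RNA genes, whose reads cannot be assigned to one copy. Alignments, isoforms and protein levels were not used here.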

Results

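Transcript levels were measured in NCI-H1693 cells kept for 6, 48 or 72 h in 50 nM PRT3789 or in its solvent DMSO. PRT3789 is a degrader selective for SMARCA2. SMARCA2 and SMARCA4 are the alternative ATPases of the SWI/SNF chromatin remodelling complexes, and the labels describe this line as lacking SMARCA4. Each of the 6 groups had 3 libraries. Totals ran from 23154484 to 31094797 counts per library, and 14743 to 15677 genes had at least 10 counts in a library. The first principal component held 49% of the variance. It placed all PRT3789 libraries of 48 and 72 h between 59.3 and 71.4, and the other 12 libraries between -55.2 and -16.3.

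Libraries of one group differed more at 6 h than later. The median SD of log2 CPM over 11059 genes was 0.167 in DMSO and 0.149 in PRT3789 at 6 h, against 0.119 and 0.0644 at 48 h and 0.0722 and 0.0669 at 72 h. Part of the difference followed transcript length. Across genes, which are not independent replicates, the Spearman correlation between length and a library's deviation from the mean of its time point was 0.507 in DMSO 6 h replicate 1, and 0.281 and 0.456 in PRT3789 6 h replicates 1 and 2. It was -0.357 and -0.462 in the other DMSO libraries of 6 h and -0.483 in PRT3789 6 h replicate 3. At 48 h it was between 0.127 and 0.207 in the PRT3789 libraries and 0.0335, -0.307 and -0.219 in the DMSO libraries. Ribosomal protein transcripts, which are short, took 7.02% ± 1.70 of counts in DMSO and 6.66% ± 1.44 in PRT3789 at 6 h, 5.19% ± 0.577 and 4.18% ± 0.202 at 48 h, and 4.05% ± 0.283 and 3.69% ± 0.1 at 72 h (SD, n = 3). Nuclear ribosomal RNA took 2.78% ± 2.11 of counts in DMSO at 6 h and between 1.51% and 2.16% on average in the other groups.

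**Figure D1:**
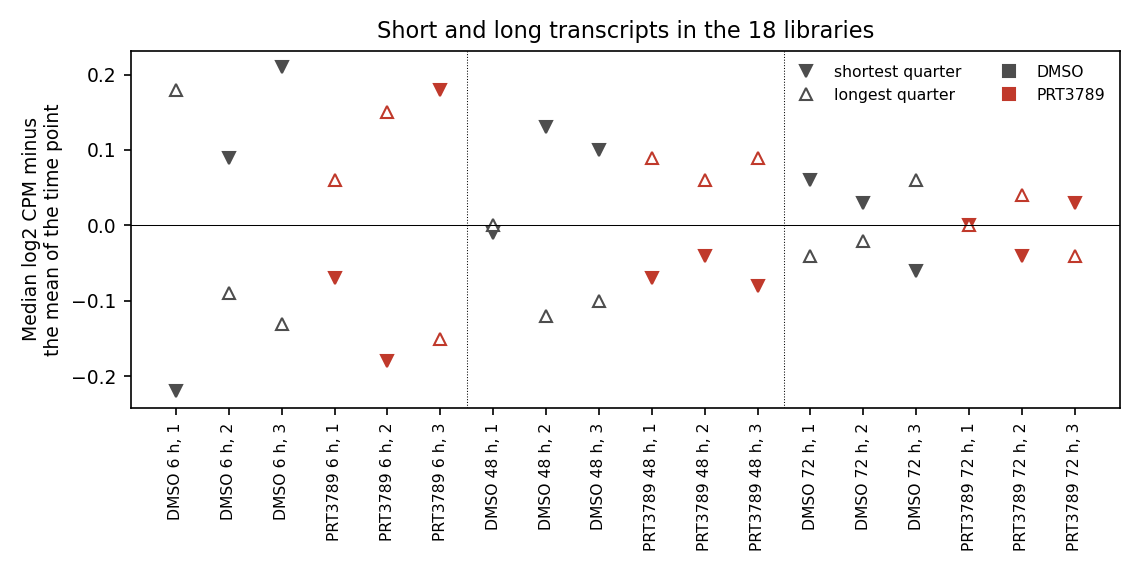
Median log2 CPM of the shortest quartile (filled triangles) and the longest quartile (open triangles) of tested genes, minus the mean of the time point, in each of the 18 libraries, DMSO in grey and PRT3789 in red. At 6 h the shortest quartile lay between -0.22 (DMSO replicate 1) and 0.21 (DMSO replicate 3); at 48 h it lay at -0.08 to -0.04 in PRT3789 and -0.01 to 0.13 in DMSO.

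SMARCA2 and 3 further genes were fixed as readouts of the treatment: the alternative ATPase SMARCA4, the keratin KRT80, and PLAU, which encodes the urokinase plasminogen activator. KRT80 (chromosome 12, 52168996 to 52192014) fell at every time. Its level went from 389 ± 38.2 CPM in DMSO to 134 ± 25.6 in PRT3789 at 6 h, from 562 ± 20.9 to 17.1 ± 1.49 at 48 h and from 634 ± 15.7 to 19.9 ± 3.23 at 72 h (SD, n = 3), which is 2.90-, 32.9- and 31.9-fold lower (adjusted p 6.28e-07, 1.01e-13 and 6.52e-14). PLAU (chromosome 10, 73908832 to 73917494) was not called at 6 h (log2FC -0.27 ± 0.22 SE, adjusted p = 0.664), then fell 7.46-fold at 48 h (-2.90 ± 0.24, adjusted p = 4.5e-08) and 12-fold at 72 h (-3.59 ± 0.25, adjusted p = 4.19e-09). At 6 h PLAU was at 175 ± 5.51 CPM in PRT3789 and 211 ± 6 in DMSO, without overlap of the libraries. At 48 h PRT3789 replicate 3 was at 58.31 CPM, against 28.74 and 21.96 in the other libraries of its group. An excess of PLAU in neighbouring libraries is described last. SMARCA2 transcript (chromosome 9, 2015347 to 2193620) was 39.4 CPM in DMSO and 40.5 in PRT3789 at 6 h (log2FC 0.04 ± 0.10, adjusted p = 0.896) and -0.19 ± 0.10 at 48 h (adjusted p = 0.126). At 72 h it fell 1.36-fold, from 47.2 ± 2.49 to 34.8 ± 2.35 CPM (adjusted p = 0.00108). SMARCA4 transcript (chromosome 19) was present at 8.38 ± 3.07 CPM in DMSO at 6 h and was not called at any time, with log2FC -0.15 ± 0.18, 0.06 ± 0.17 and -0.22 ± 0.17 (adjusted p 0.778, 0.816 and 0.318).

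**Figure D2:**
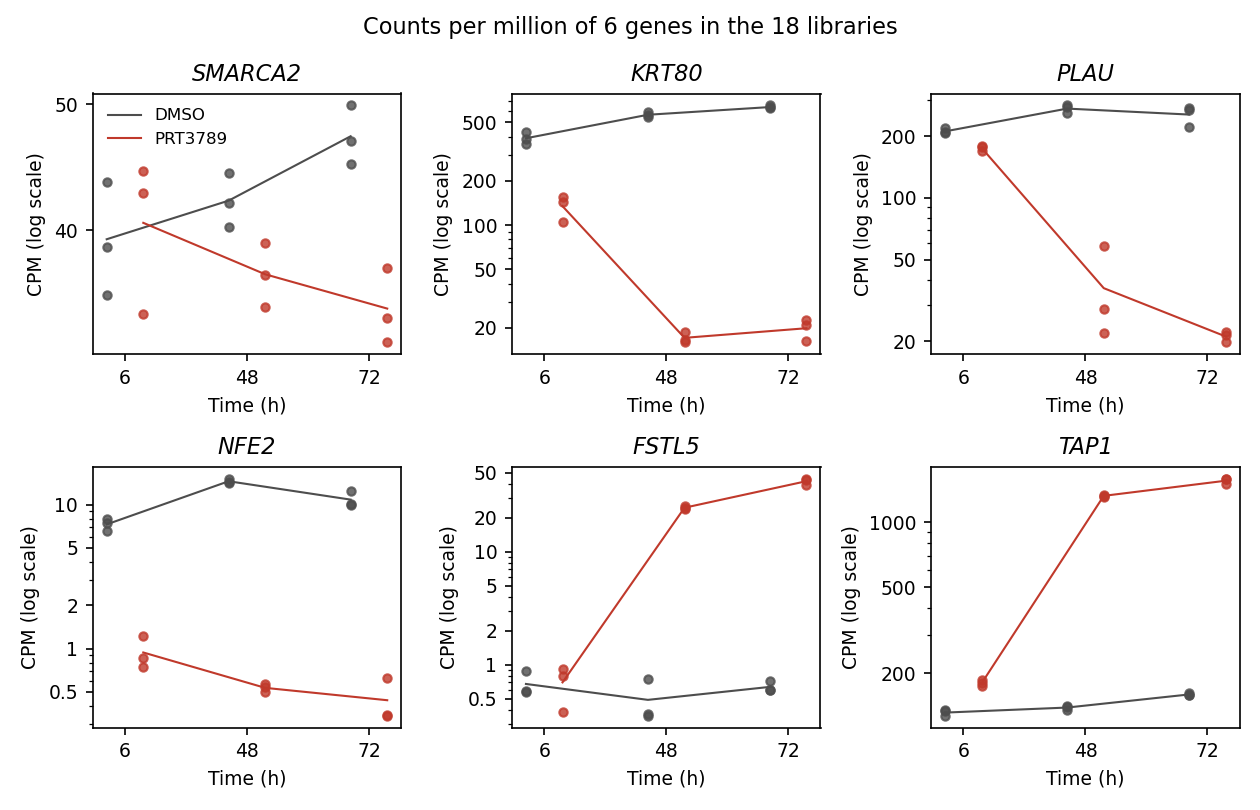
CPM on a log axis of 6 genes in each library, DMSO in grey and PRT3789 in red, with lines through the group means; time points are evenly spaced, not to scale. KRT80 and NFE2 were called lower with PRT3789 at 6 h already. PLAU was called lower from 48 h, though its PRT3789 libraries lay below those of DMSO at 6 h too. FSTL5 and TAP1 reached 24.6 and 1320 CPM with PRT3789 at 48 h.

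The 6 h comparison is the earliest time sampled, and changes before it were not measured. NOG, a secreted BMP antagonist, rose 2.90-fold from 13.4 ± 1.6 to 38.7 ± 2.47 CPM (log2FC 1.53 ± 0.09, adjusted p = 1.92e-08), and GLI1, a transcription factor of the Hedgehog pathway, rose 2.65-fold (1.40 ± 0.15, adjusted p = 9.53e-06). Other rises were SLITRK5 (2.44-fold), the matrix protease ADAMTS5 (2.12-fold), the TEAD cofactor VGLL2 (1.92-fold), the MAP kinase phosphatase DUSP4 (1.88-fold), CCDC184 (1.85-fold), the non-coding RNA MIR1915HG (1.84-fold), the phosphate transporter SLC34A2 (2.40-fold) and HIVEP2-DT (2.12-fold). SLC34A2 showed a like excess in the libraries 8 places later, as described last, so its rise is not shown to be a response to PRT3789. The largest fall was in NFE2, an erythroid and megakaryocytic transcription factor, from 7.29 ± 0.707 to 0.939 ± 0.249 CPM (log2FC -2.95 ± 0.18, adjusted p = 1.74e-08). The adhesion molecule NECTIN4 fell 3.16-fold, from 47.0 ± 2.57 to 14.9 ± 2.80 CPM, and the Wnt ligand WNT7A 2.99-fold. RBBP8NL, LINC02967, ZBED2, CRYBG2, BCAR4 and MAB21L4 fell 3- to 3.49-fold, as did RNA45SN3, a precursor of ribosomal RNA whose reads cannot be assigned to one gene copy (3.24-fold).

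In total 209 genes were higher and 496 lower at 6 h, 4.33% of the 16291 tested, and 22 and 145 of them changed at least 2-fold; 2365 genes had an unadjusted p under 0.05. With the 6 h libraries fitted apart, 21 genes were higher and 126 lower. Of the 705 calls of the joint model, 139 were called in the same direction in that fit. In simulated counts where each time kept its own spread, most 6 h calls of the joint model were false, while the fit apart found fewer planted changes. Many of the 705 calls may thus be false. Scaling by total counts raised the share of higher genes among the calls from 29.6% to 44.3% (293 higher, 368 lower). The count of higher genes was 574 without DMSO 6 h replicate 1, 131 without DMSO replicate 2, 125 without DMSO replicate 3, 130 without PRT3789 replicate 1 and 121 without PRT3789 replicate 2. The fit apart ended the calls of ADAMTS5, VGLL2, DUSP4, MIR1915HG, BCAR4, HIVEP2-DT and RNA45SN3 (adjusted p 0.0562 to 0.299). SLC34A2 was not called without any one of the 6 h libraries (adjusted p 0.0751 to 0.158), HIVEP2-DT without DMSO replicates 2 or 3 or PRT3789 replicates 1 or 2 (0.0893 to 0.194), and RNA45SN3 without DMSO replicate 2 or any one of the PRT3789 libraries (0.079 to 0.213). Without DMSO replicate 2 the log2FC of RNA45SN3 went from -1.70 to -0.88. The calls of SLC34A2 and RNA45SN3 also ended without a filter and with either replicate block, that of SLC34A2 with the length trend removed, that of RNA45SN3 in limma-voom, and that of HIVEP2-DT in limma-voom and with the block over all groups (0.0598 to 0.201). NOG, GLI1, SLITRK5, CCDC184, NFE2, NECTIN4, WNT7A and KRT80 were called under every alternative run on single genes. The stricter thresholds were run on counts only, and CCDC184 changed less than 2-fold.

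Interferon-stimulated genes fell at 6 h. Of 41 measured, 11 fell and 1 rose (15 and 1 adjusted over the list alone), among them GBP3 (log2FC -0.88), SAMD9L (-0.96), IFIT3 (-1.20) and IFIT2 (-1.02); the median log2FC was -0.35 and the camera adjusted p 2.27e-09 (adjusted p = 0.0828 with an estimated correlation). The one that rose was IRF1 (0.24), named after its values were seen. Epithelial junctions and keratins fell in 7 of 45, and the other 38 did not pass (7 fell adjusted over the list alone), with the epithelial transcription factor ELF3 at -1.28, the claudin CLDN4 at -1.07 and the tight junction protein MARVELD3 at -0.64 beside KRT80 (adjusted p = 2.12e-05; adjusted p = 0.311 with an estimated correlation). Without DMSO 6 h replicate 1 that list had an adjusted p of 0.0564. Apoptosis regulators fell in 4 of 22 (8 fell and 1 rose adjusted over the list alone), among them BCL2L1 (-0.38), BIK (-1.29) and BMF (-0.64), with adjusted p = 0.00536 (adjusted p = 0.0828 with an estimated correlation).

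Targets of growth and stress signals moved as follows at 6 h. Among MAPK feedback genes 6 of 25 fell and 2 rose (8 and 3 adjusted over the list alone): the growth factor HBEGF (-0.67), the receptor EPHA2 (-1.06), IER3 (-1.13) and the cytokine LIF (-1.24) fell. The list had adjusted p = 0.0237 (adjusted p = 0.224 with an estimated correlation), with 0.115 without DMSO 6 h replicate 1, 0.0644 without PRT3789 6 h replicate 3 and 0.0824 without a filter. Cell cycle inhibitors and p53 targets fell in 4 of 29 and rose in 1 (7 and 1 adjusted over the list alone). CDKN1A, the inhibitor p21, was at -0.58, PHLDA3 at -0.84 and GADD45A at -0.49, while CDKN2B rose (0.37). That list had adjusted p = 0.0201 (adjusted p = 0.311 with an estimated correlation), 0.0657 without DMSO 6 h replicate 3 and 0.0817 without PRT3789 6 h replicate 2. TGF-beta and BMP targets rose in 4 of 28 and fell in 1 (6 and 3 adjusted over the list alone), with NOG, TGIF1 (0.46), ID4 (0.61) and ID2 (0.73) among them (adjusted p = 0.00401; adjusted p = 0.264 with an estimated correlation). The unfolded protein and integrated stress response fell in 4 of 34 (7 adjusted over the list alone), among them the transcription factor XBP1 (-0.36) and SLC3A2 (-0.29), with adjusted p = 0.0279 (adjusted p = 0.589 with an estimated correlation). Its call ended without DMSO 6 h replicate 1 (0.209), without PRT3789 6 h replicate 3 (0.199) and with total counts, the length trend removed or the time fitted apart (0.0669 to 0.0737).

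NF-kB and cytokine genes at 6 h had RELB (0.72) and TNFAIP3 (0.78) higher and NFKBIA (-0.58) lower among 29 (the same counts adjusted over the list alone; adjusted p = 0.0014, and adjusted p = 0.311 with an estimated correlation). Lung epithelial lineage genes had 1 of 21 called, SLC34A2, whose rise is not shown to be a response, and 6 higher adjusted over the list alone (adjusted p = 0.00485, adjusted p = 0.336 with an estimated correlation, and 0.0643 without DMSO 6 h replicate 1). Of these lists, 7 NF-kB members and 8 lung members belonged to the genes found in neighbouring libraries that are described last, and with such genes taken out of the lists the adjusted p was 0.0293 and 0.0473. In a fit without such genes the lung list had 0.055. The S phase and G2/M phase lists were not called at 6 h (median log2FC -0.0114 and -0.0592, adjusted p 0.804 and 0.435). Of the 78 genes called at 6 h that the naming rule took, 29 were called under every alternative apart from the stricter thresholds, which were run on counts only. The calls of IFIT2, BCL2L1, BIK, BMF, GADD45A, CDKN2B, TGIF1, ID4, ID2, XBP1, SLC3A2, RELB, NFKBIA and TNFAIP3 ended with the time fitted apart. That of TNFAIP3 also ended without DMSO 6 h replicate 2 (0.0523) and that of SLC3A2 with total counts (0.0545).

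At 48 h the treated cells differed from DMSO in many transcripts, and several genes moved from near absence to a high level or the reverse. FSTL5, a follistatin-like secreted protein, rose 50.6-fold from 0.488 ± 0.223 to 24.6 ± 0.817 CPM (log2FC 5.66 ± 0.21, adjusted p = 9.42e-13), and GASK1B, a Golgi-associated kinase-like protein, 38.7-fold from 4.61 ± 0.658 to 178 ± 10.4 CPM (5.27 ± 0.14, adjusted p = 2.32e-14). TAP1, a subunit of the transporter that loads peptides onto MHC class I, rose 9.57-fold from 138 ± 2.59 to 1320 ± 15.9 CPM (3.26 ± 0.06, adjusted p = 2.78e-16). VGLL2, the G protein regulator RGS2, HIVEP2-DT, the zinc finger factor PLAGL1, the collagen COL3A1, KITLG (ligand of the receptor KIT) and the nuclear receptor HNF4G rose 6.99- to 8.85-fold. VTCN1, an inhibitory immune ligand, fell 85.2-fold from 37.6 ± 1.61 to 0.433 ± 0.241 CPM (-6.41 ± 0.20, adjusted p = 1.40e-13). The GABA receptor subunit GABRP fell 63.8-fold, the troponin TNNT2 54.8-fold, the proton pump subunit ATP6V1B1 36.5-fold and the alkaline phosphatase ALPP 35-fold. SPRR3 and IVL, proteins of the cornified envelope, fell 34.5- and 24.7-fold, NFE2 27.0-fold, and TLR7, a receptor for RNA, 25.7-fold. In total 3451 genes were higher and 3402 lower, 42.1% of those tested, of which 714 and 1093 at least 2-fold.

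At 72 h FSTL5 and GASK1B again showed the largest rises, and TNNT2 and VTCN1 the largest falls, under the naming rule. FSTL5 rose 66.2-fold from 0.636 ± 0.0645 to 42.3 ± 3.03 CPM (log2FC 6.05 ± 0.20, adjusted p = 1.58e-13), GASK1B 36.1-fold, VGLL2 10.6-fold, TAP1 9.78-fold to 1560 ± 51.7 CPM, COL3A1 9.75-fold, HNF4G 9.33-fold, KITLG 8.32-fold, RGS2 by 3.64 on the log2 scale, HIVEP2-DT 7.89-fold and the ciliary protein CYS1 7.54-fold. TNNT2 fell 80.2-fold (-6.33 ± 0.42, adjusted p = 1.97e-09), VTCN1 68.7-fold, SPRR3 67.4-fold, ALPP 50.9-fold, GABRP 47.3-fold, ATP6V1B1 33.3-fold, TLR7 31.9-fold and the chloride channel protein CLIC5 29.7-fold. GBP2, an interferon-induced GTPase, fell 32.4-fold from 46.3 ± 0.942 to 1.43 ± 0.325 CPM (-5.02 ± 0.16, adjusted p = 1.47e-13). In total 3478 genes were higher and 3591 lower, 43.4% of those tested, of which 864 and 1220 at least 2-fold.

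**Figure D3:**
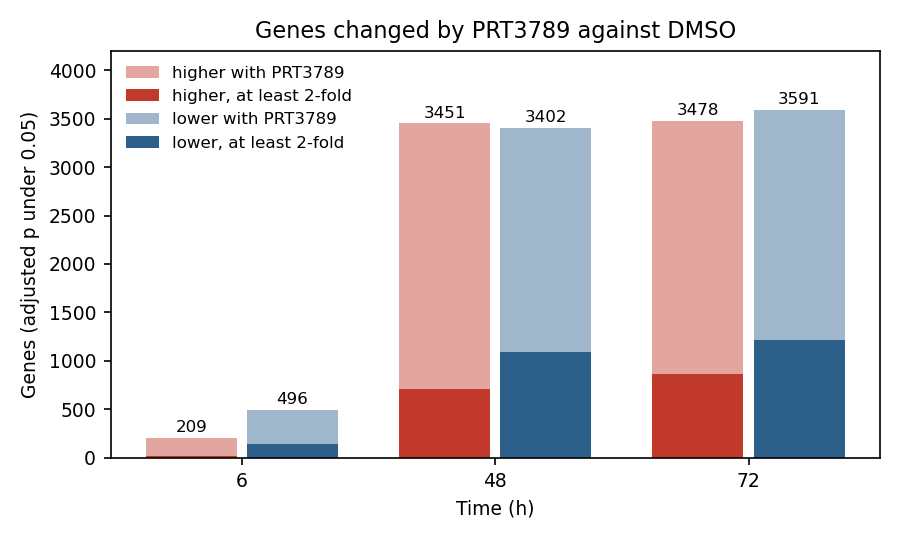
Number of genes higher (red) and lower (blue) with PRT3789 than with DMSO at each time point, 3 libraries per group, with the dark part of each bar changed at least 2-fold. The calls went from 209 higher and 496 lower at 6 h to 3478 and 3591 at 72 h.

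Cell cycle genes fell together at 48 and 72 h. Of 54 genes of G2/M phase, 46 fell at 48 h and 49 at 72 h, and the other 8 and 5 did not pass (48 and 49 fell adjusted over the list alone), with medians of -0.745 and -0.902 and adjusted p of 9.34e-18 and 2.17e-22. These were the only list calls of 27 that held with an estimated correlation (adjusted p = 0.00297 and 0.00148). CDCA8 was at -0.90 ± 0.06 and -1.01 ± 0.06 at these times and CDC20, an activator of the anaphase-promoting complex, at -0.92 and -0.97; CDC25C was at -1.22 and CDCA3 at -1.38 at 48 h, and KIF2C at -0.98 and GTSE1 at -1.20 at 72 h. Of 43 S phase genes, 23 fell at 48 h and 37 at 72 h, and the other 20 and 6 did not pass (23 and 38 fell adjusted over the list alone). FEN1 was at -0.49 and -0.59, the ribonucleotide reductase subunit RRM2 at -0.50 and -0.68, TYMS at -0.74 at 48 h and CDC6 at -0.68 at 72 h (adjusted p 0.0039 and 5.62e-07; adjusted p = 0.336 and 0.155 with an estimated correlation). Homologous recombination and Fanconi anaemia genes had 10 of 32 lower and 5 higher at 48 h (adjusted p = 0.695) and 17 lower and 1 higher at 72 h (adjusted p = 0.0417; adjusted p = 0.654 with an estimated correlation), with FANCI at -0.56, XRCC2 at -1.01 and RAD54L at -0.84. The 72 h call of that list ended without DMSO 72 h replicate 2 (0.0547), DMSO 72 h replicate 3 (0.0514) or PRT3789 72 h replicate 3 (0.0556). It also ended with total counts, the 1 CPM filter, either replicate block or the time fitted apart (0.0522 to 0.0972). Among cell cycle inhibitors and p53 targets 7 of 29 rose and 8 fell at 48 h and 9 and 9 at 72 h (adjusted p 0.695 and 0.661). CDKN1A fell (-1.51 and -1.06) and CDKN2B, the inhibitor p15, rose (1.18 and 1.40).

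Epithelial, mesenchymal and adhesion genes fell more often than they rose at both later times. Of 45 epithelial junction and keratin genes 24 fell and 11 rose at 48 h, and 22 and 7 at 72 h (25 and 11, and 25 and 9, adjusted over the list alone). Beside KRT80, the keratin KRT81 fell (-2.16 and -1.99) and CLDN4 fell (-1.33 and -1.40), while the claudin CLDN1 rose (1.19 and 1.34); the adjusted p was 5.82e-05 and 3.34e-05 (adjusted p = 0.316 and 0.311 with an estimated correlation). Of 37 mesenchymal genes 20 fell at each time, and 5 and 4 rose (the same counts adjusted over the list alone), with medians of -1.05 and -0.953 (adjusted p 5.32e-07 and 1.01e-07; adjusted p = 0.122 and 0.0828 with an estimated correlation). The matrix protein SPARC was at -2.68 and -3.24, the transcription factor SNAI2 at -2.22 and -2.64, the actin-binding TAGLN at -2 and -2.72 and the protease MMP2 at -2.01 and -2.50. Integrin and adhesion genes fell in 14 and 15 of 27 and rose in 3 and 2 (the same adjusted over the list alone), with L1CAM at -3.81 and -4.52, the integrin ITGB6 at -1.92 and -1.88, CADM1 at -1.36 and -1.62 and NECTIN4 at -1.62 and -1.90 (adjusted p 0.000593 and 3.34e-05; adjusted p = 0.311 and 0.264 with an estimated correlation). Collagen and matrix genes had 10 higher and 17 lower of 36 at 48 h and 8 and 16 at 72 h (adjusted p 0.695 and 0.42), with TIMP1 at -1.69 and -1.98 against COL3A1 in the other direction. Some of these falls were of genes found in neighbouring libraries, described last. They were 1 mesenchymal and 1 integrin gene at each time, and 2 collagen and matrix genes at 48 h and 1 at 72 h. Those falls are not shown to be a response to PRT3789. YAP/TEAD targets had 12 higher and 10 lower of 33 at 48 h (adjusted p = 0.323) and 10 and 17 at 72 h (11 and 17 adjusted over the list alone; adjusted p = 0.0279, and adjusted p = 0.74 with an estimated correlation). F3, the tissue factor, was at -1.77, CCN2 at -1.64, IGFBP3 at -1.45 and FJX1 at -1.37 at 72 h. The list call ended without PRT3789 72 h replicate 3 (0.0507) or without a filter (0.0541).

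**Figure D4:**
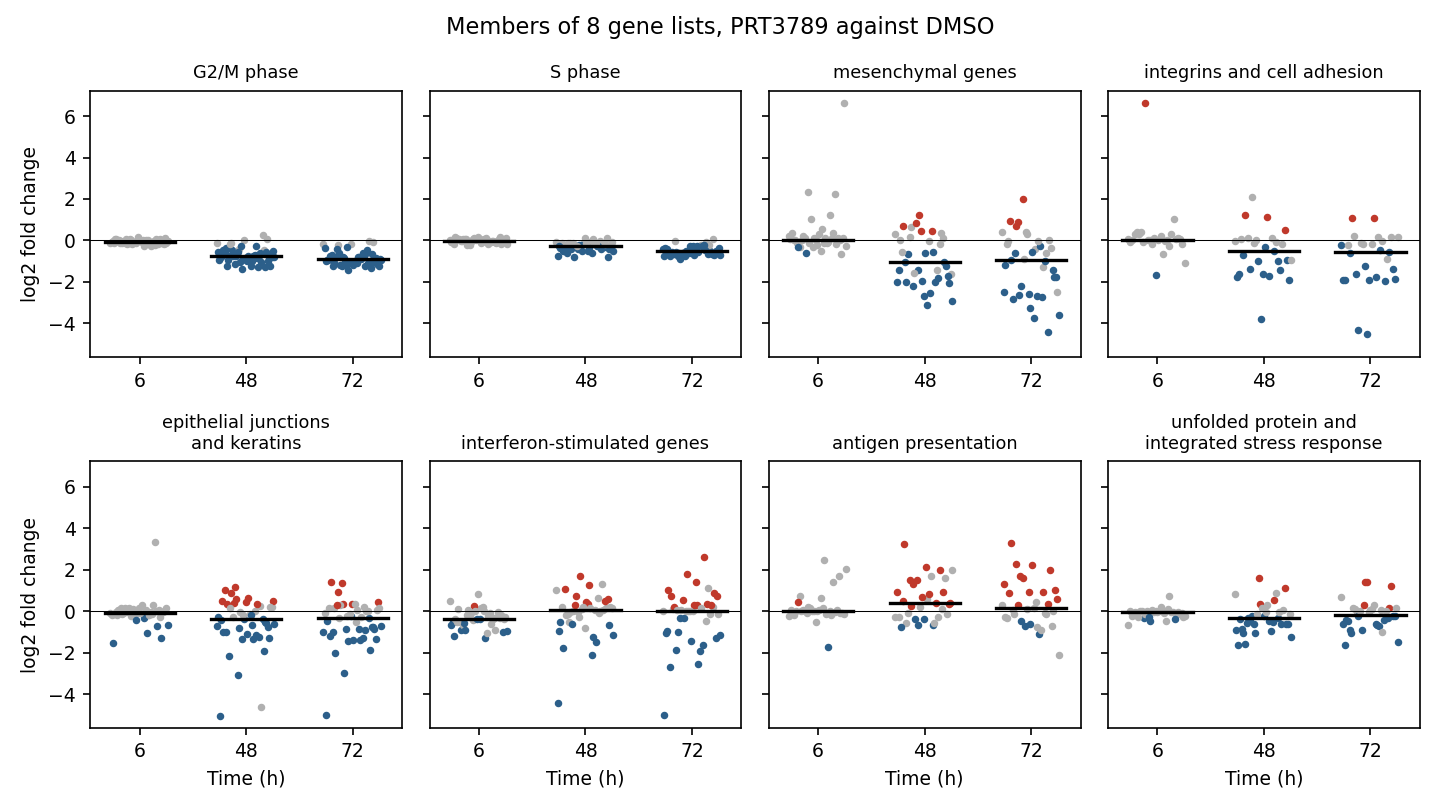
Log2 fold change with PRT3789 against DMSO of each measured member of 8 gene lists by time point, red for members that rose, blue for those that fell, grey for those not called, with a black bar at the list median. The G2/M phase median went from -0.0592 at 6 h to -0.745 at 48 h and -0.902 at 72 h.

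Antigen presentation genes rose at 48 and 72 h. Of 33 measured, 15 rose and 5 fell at 48 h and 14 rose and 4 fell at 72 h (15 and 5, and 14 and 6, adjusted over the list alone), with adjusted p of 0.000243 and 2.12e-05 (adjusted p = 0.336 and 0.311 with an estimated correlation). TAP2, the partner of TAP1, rose by 1.49 ± 0.06 and 1.6, the MHC molecule HLA-E by 0.93 and 1.31, and the immunoproteasome subunit PSMB9 by 2.12 ± 0.16 and 2.25. PSMB8, named after its values were seen, rose by 1.33 and 1.68. TAP2, PSMB8, TAP1 and PSMB9 lie next to one another on chromosome 6 from 32821831 to 32859851. Interferon-stimulated genes went both ways, with 9 of 41 higher and 10 lower at 48 h and 13 and 14 at 72 h (adjusted p 0.872 and 0.807): GBP2 fell (-4.45 at 48 h), and the transcription factor IRF1 (1.70 and 1.79) and the RNA sensor IFIH1 (1.29 and 1.42) rose. NF-kB and cytokine genes had 8 of 29 higher at each time, with 7 lower at 48 h and 8 at 72 h (adjusted p 0.311 and 0.575); BIRC3 (1.55), RELB (1.64) and NFKB2 (1.31) rose at 48 h. Of the lower NF-kB genes, 3 at 48 h and 4 at 72 h belonged to the genes found in neighbouring libraries that are described last, so that these falls are not shown to be a response to PRT3789. Blood cell markers had 1 of 6 called, the receptor CSF1R, at -3.32 and -3.68 (adjusted p 0.706 and 0.807). Endothelial and fibroblast markers had 3 higher and 4 lower of 11, then 2 and 4 (adjusted p 0.695 and 0.804), with ESAM at -2.57 and CDH5 at -6.32 at 48 h.

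Signalling lists went in both directions at 48 and 72 h. TGF-beta and BMP targets had 5 of 28 higher and 14 lower at 48 h and 7 and 15 at 72 h (adjusted p 0.0888 and 0.168), with PMEPA1 at -2.33 and BMP4 at -1.32 at 48 h. Wnt and Notch genes had 7 of 27 higher and 9 lower, then 9 and 10 (adjusted p 0.578 and 0.493), with WNT7A at -3.43 and WNT7B at -2.23 at 48 h. MAPK feedback genes had 9 of 25 higher and 8 lower, then 8 and 10 (adjusted p 0.427 and 0.164), with LIF at -2.62 and -2.71. AP-1 factors had 6 of 15 higher and 4 lower, then 5 and 3 (adjusted p 0.294 and 0.418): ATF3 rose (1.6) and FOSL1 fell (-1.70) at 48 h. Immediate early and heat shock genes had 7 of 24 higher and 9 lower, then 5 and 8 (adjusted p 0.8 and 0.579), with KLF4 (1.81) and NR4A3 (3.21) higher and IER5 (-1.72) lower at 48 h. MYC and its targets had 5 of 32 higher and 12 lower, then 1 and 13 (adjusted p 0.462 at both times), with MYCN at -1.01 at 48 h and MYC at -0.76 at 72 h. Apoptosis regulators had 6 of 22 higher and 8 lower, then 7 and 8 (adjusted p 0.872 and 0.642), with BIRC3 higher and the BH3-only gene BMF lower (-1.35 and -2.04). At 6 h the lists of MYC (1 higher, 1 lower), AP-1 (2 lower), immediate early (2 and 2), YAP/TEAD (2 and 5) and Wnt and Notch genes (2 and 4) were not called (adjusted p 0.632, 0.825, 0.706, 0.129 and 0.872).

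Metabolic and stress genes went in both directions. The unfolded protein and integrated stress response fell in 21 of 34 and rose in 4 at 48 h (21 and 5 adjusted over the list alone), with the amino acid transporter subunit SLC3A2 at -1.04, STC2 at -1.56 and the serine enzyme SHMT2 at -1.03 against ATF3 at 1.6 (adjusted p = 0.000851; adjusted p = 0.316 with an estimated correlation); at 72 h 16 fell and 5 rose (adjusted p = 0.185). Cholesterol synthesis fell in 13 of 26 and rose in 1 at 48 h (adjusted p = 0.093) and fell in 15 and rose in 2 at 72 h, adjusted over the list alone too (adjusted p = 0.0237; adjusted p = 0.224 with an estimated correlation). INSIG1 was at -1.41, MVK, mevalonate kinase, at -0.78, ACAT2 at -0.77 and the reductase TM7SF2 at 1.28. Fatty acid and lipid genes had 6 of 26 higher and 3 lower, then 7 and 11 (adjusted p 0.427 and 0.991), with DGAT2 at 1.22 and 1.66. Hypoxia and glycolysis genes had 12 of 35 higher and 11 lower, then 9 and 17 (adjusted p 0.791 and 0.293): the glucose transporter SLC2A1 fell (-2.81 and -2.92) and adrenomedullin, ADM, rose (2.05 and 2.49). NRF2 targets had 2 of 27 higher and 11 lower, then 4 and 11 (adjusted p 0.0638 and 0.176), with TKT at -1 and -1.19 and FTH1 at -0.80 at 48 h. Of the lower NRF2 targets at 72 h, 1 belonged to the genes found in neighbouring libraries, so its fall is not shown to be a response. Ribosomal proteins fell in 17 of 56 at 48 h (11 adjusted over the list alone; adjusted p = 0.0279, and adjusted p = 0.944 with an estimated correlation), with RPLP2 at -0.53 and RPLP0 at -0.65, and in 8 at 72 h (2 adjusted over the list alone; adjusted p = 0.458). The 48 h call ended without DMSO 48 h replicate 2 (0.073) or replicate 3 (0.0668). Over all genes the shortest transcripts had a median log2FC of -0.14 and the longest of 0.15 at 48 h, against -0.01 and 0 at 72 h. Oxidative phosphorylation had 8 of 38 lower at 48 h (0 adjusted over the list alone) and none called at 72 h (adjusted p 0.231 and 0.804), the proteasome 7 of 31 lower, then 1 higher and 4 lower (adjusted p 0.42 and 0.795), with PSMD6 at -0.48 at 48 h, and mitochondrially encoded genes 1 of 13 higher, MT-ND6, then none (adjusted p 0.427 and 0.695). The call of MT-ND6 ended without DMSO 48 h replicates 2 (0.0624) or 3 (0.0842), without PRT3789 48 h replicates 1 (0.0739) or 3 (0.067), with the length trend removed (0.0948) and with the time fitted apart (0.129). At 6 h the cholesterol (1 higher), fatty acid, hypoxia (2 higher, 4 lower), NRF2 (2 lower), oxidative phosphorylation, ribosomal protein, proteasome and mitochondrial lists had adjusted p of 0.0888, 0.463, 0.464, 0.558, 0.493, 0.23, 0.695 and 0.872.

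No list of chromatin genes was called at any time. SWI/SNF subunits had 12 of 27 higher and 4 lower at 48 h, and 6 and 5 at 72 h (adjusted p 0.458 and 0.706, and 0.178 at 6 h); SMARCD2 fell (-0.49 and -0.63), BRD7 fell (-0.35 at 48 h) and ARID1A rose (1.07 at 48 h). Other remodellers had 6 of 17 higher at 48 h, with SMARCAL1 at 0.39, and 1 higher and 2 lower at 72 h (adjusted p 0.231 and 0.872), with HELLS at -0.55. Polycomb complexes had 7 of 25 higher and 4 lower, then 5 and 5 (adjusted p 0.575 and 0.994), with EZH1 at 0.81 and PHF19 at -0.49 at 48 h. VHL ubiquitin ligase genes had 2 of 16 higher and 1 lower at both times, with UBE2R2 at 0.49 at 48 h (adjusted p 0.994 and 0.804). Lung epithelial lineage genes had 4 of 21 higher and 7 lower, then 3 and 7 (adjusted p 0.994 and 0.915). Of the lung genes, 1 higher and 3 lower at 48 h and 4 lower at 72 h belonged to the same genes found in neighbouring libraries, so that these changes are not shown to be a response either. Neuroendocrine and neuronal genes had 5 of 11 higher and 3 lower at both times (7 and 4 at 72 h adjusted over the list alone). MAP2 rose (1.61 and 1.77), the synaptic vesicle protein SYP rose (2.93 and 2.44), CHGB rose (2.56 and 2.54) and ENO2 fell (-0.94 and -1.23), with adjusted p of 0.0638 and 0.0428 (adjusted p = 0.251 and 0.224 with an estimated correlation). The 72 h call of that list ended without DMSO 72 h replicate 2 (0.0678), DMSO 72 h replicate 3 (0.0534) or PRT3789 72 h replicate 3 (0.0507). It also ended without a filter, with the 1 CPM filter, in DESeq2 and limma-voom, with either replicate block, with the length trend removed and with the time fitted apart (0.061 to 0.236). At 6 h the lists of other remodellers, polycomb, VHL, collagen, blood, and endothelial and fibroblast genes were not called (adjusted p 0.173, 0.0737, 0.695, 0.458, 0.344 and 0.586). Homologous recombination, mesenchymal (2 lower), integrin (1 and 1, the higher one CEACAM6, a gene found in neighbouring libraries), antigen presentation (1 and 1, with TAP1 at 0.46, whose call ended with the time fitted apart at 0.0578) and neuroendocrine genes (2 and 1) had adjusted p of 0.0511, 0.804, 0.91, 0.317 and 0.455 at 6 h.

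Adjusted over the list alone, the counts of lists that were not called differed from those given by at most 3 genes per direction, apart from oxidative phosphorylation at 48 h and ribosomal proteins at 72 h, given above. Median, mean and test direction of a list differed in sign at 6 h for S phase, VHL, AP-1, MAPK feedback, Wnt and Notch, and endothelial and fibroblast genes, at 48 h for VHL, apoptosis, interferon-stimulated and NF-kB genes, and at 72 h for VHL, p53 targets, interferon-stimulated, NF-kB, Wnt and Notch, and blood cell genes. For MAPK feedback at 6 h, the only called list among these, the median was -0.0806 and the mean 0.0405.

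Whether the effect of PRT3789 changed between times was tested directly. Between 6 and 48 h the effect rose for 1438 genes and fell for 1694. This contrast takes in the 6 h libraries under the spread pooled over times. Neither the fit apart nor the simulation covered it, so its share of false calls was not measured. GASK1B (difference in log2FC 5.04 ± 0.19, adjusted p = 7.98e-12), FSTL5 (5.63 ± 0.41, adjusted p = 3.47e-08) and HNF4G (2.89 ± 0.27, adjusted p = 6.48e-07) gained most, and VTCN1 (-5.71 ± 0.25), TNNT2 (-5.65 ± 0.54), GABRP (-5.55 ± 0.30), ALPP (-4.94 ± 0.25) and SPRR3 (-4.84 ± 0.32) lost most. KRT80 fell further (-3.51 ± 0.18, adjusted p = 5.24e-10), as did PLAU (-2.63 ± 0.32, adjusted p = 1.58e-05); SMARCA2 differed by -0.23 ± 0.13 (adjusted p = 0.277) and SMARCA4 by 0.21 ± 0.24 (adjusted p = 0.625). The ribosomal RNA genes RNA5-8SN1 and RNA5-8SN2, whose reads cannot be told apart, were at 2.87 ± 0.93 (adjusted p = 0.0432), and at 1.38 (adjusted p = 0.144) without DMSO 6 h replicate 2. Their call ended in 13 of 22 alternatives. Beside that one, these were the fits without any one of the PRT3789 libraries of 6 h or DMSO libraries of 48 h, without PRT3789 48 h replicates 1 or 2, without a filter, limma-voom and either replicate block (0.0613 to 0.24). Between 48 and 72 h no gene was called in edgeR, where 1476 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0582. Limma-voom also called 0, and DESeq2 called 65 higher and 38 lower. Without DMSO 48 h replicate 1 edgeR called 7 and 1, and without PRT3789 72 h replicate 1 it called 1 lower.

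Genes called at 6 h mostly moved the same way later. Of the 209 higher at 6 h, 174 (83.3%) were higher at 48 h, where 44.3 would be shared if the calls were independent, and 173 were higher at 72 h. Of the 496 lower at 6 h, 423 (85.3%) were lower at 48 h against 104 if independent, and 416 were lower at 72 h. At 48 and 72 h 2575 genes were higher and 2739 lower at both times, with 3 and 1 called in opposite directions. Across all genes, which are not independent replicates, the correlation of log2FC was 0.239 between 6 and 48 h and 0.824 between 48 and 72 h. With the time points fitted apart, 131 of the calls at 6 h were shared with 48 h, against 597. A set of 14 genes was called in one direction at 6 h and in the other at both later times. The set includes SLC34A2, whose 6 h rise is not shown to be a response. It also includes LOC124900388 and LOC728392, which had the same values. Chosen from this set after their values were seen, CYP24A1, the vitamin D hydroxylase, went from 0.42 to -1.90 and -2.28. GADD45A went from -0.49 to 0.73 and 1.27, and CYBRD1 from -0.30 to 0.90 and 1.19. The 6 h call of GADD45A ended with the time fitted apart.

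In DMSO alone, transcripts also changed with time in culture. Between 6 and 48 h the immediate early factors FOSB (log2FC 2.72 ± 0.33, adjusted p = 1.13e-05) and EGR1 (2.41 ± 0.10, from 41.9 ± 4.70 to 222 ± 24.1 CPM) and the pump subunit ATP6V1B1 (2.10 ± 0.12) rose. The neuropeptide gene GAL fell 11.9-fold, the protease MMP9 8.78-fold from 142 ± 20.6 to 16.2 ± 1.77 CPM, and TAGLN 6.30-fold. In total 2781 genes were higher and 3278 lower at 48 h, 37.2% of those tested. This contrast also takes in 6 h libraries under the spread pooled over times, and its share of false calls was not measured. Total-count scaling moved the median of all genes to 0.108 and gave 3793 higher and 2090 lower, a share of higher genes of 64.5% in place of 45.9%. The shortest transcripts had a median log2FC of -0.22 and the longest of 0.16 over this interval. Between 48 and 72 h 63 genes were higher and 25 lower, with EGR1 (1.11 ± 0.10, adjusted p = 1.75e-05) and MMP9 (-1.64 ± 0.12, adjusted p = 1.46e-06) among them, and FOSB (1.55), NR4A1 (1.04), SPRR3 (-0.88) and EIF4EBP3 (-0.68) with adjusted p of 0.0185, 0.0185, 0.0263 and 0.0354. The shortest transcripts had a median of -0.16 and the longest of 0.17. Higher genes numbered 29 without DMSO 48 h replicate 2, 17 without DMSO 48 h replicate 3, and 32, 24 and 20 without DMSO 72 h replicates 1, 2 and 3; lower genes numbered 4, 2, 4, 11 and 2. The call of FOSB ended without DMSO 48 h replicate 3 (0.118) or DMSO 72 h replicates 1 (0.0805) or 2 (0.0509), and that of NR4A1 without DMSO 48 h replicates 2 (0.0859) or 3 (0.123) or DMSO 72 h replicate 1 (0.0919). SPRR3 was not called without any one of the DMSO libraries of 48 h (0.0515, 0.0582 and 0.136) or without DMSO 72 h replicates 2 (0.11) or 3 (0.177), nor EIF4EBP3 without any one of the 6 libraries (0.0589 to 0.18). The call of FOSB also ended without a filter (0.0625). Those of SPRR3 and EIF4EBP3 ended with the length trend removed (0.126 and 0.0801), and that of EIF4EBP3 with the block over all groups (0.0527).

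Some genes near 0 in most libraries appeared in neighbouring libraries of the listed order, across group borders. Surfactant genes SFTPA2 and SFTPA1 and CEACAM6, PLAT and HOPX were seen in libraries 4 to 6 and again in 12 to 14, CLEC4E, the chemokines CXCL6 and CXCL8, SPP1 and MMP7 in 5 to 7 and 13 to 15, and KRT14, KRT5, KRT6A and IL1A in 6 to 8 and 14 to 16; all were chosen after their values were seen. A search of 10 runs of 3 libraries found 26 genes higher in a single run and 0 lower, and 63 genes higher in a pair of runs 8 libraries apart, against 0 or 1 gene for runs 7, 9 or 10 apart. In simulated counts where each time kept its own spread, the search of single runs gave 193 false genes higher and 235 lower. The 26 may hold false ones. Of the 63 genes, 1 was called higher at 6 h, 1 higher and 20 lower at 48 h, and 24 lower at 72 h. SLC34A2 and PLAU were not among the 63. In library 12 SLC34A2 was 10.3 CPM above the other PRT3789 libraries of 48 h, and in libraries 13 and 14 it was 10.7 CPM above the other DMSO library of 72 h. At 6 h the PRT3789 group, which is libraries 4 to 6, was 10.5 CPM above DMSO. For PLAU the same values were 33.0, 51.5 and -36.1 CPM. The 6 h rise of SLC34A2 may thus belong to this pattern and is not shown to be a response to PRT3789. The PLAU levels in these libraries may hold such an excess too, which was not tested. The order of libraries on a plate and their index sequences are not given in the labels.

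**Figure D5:**
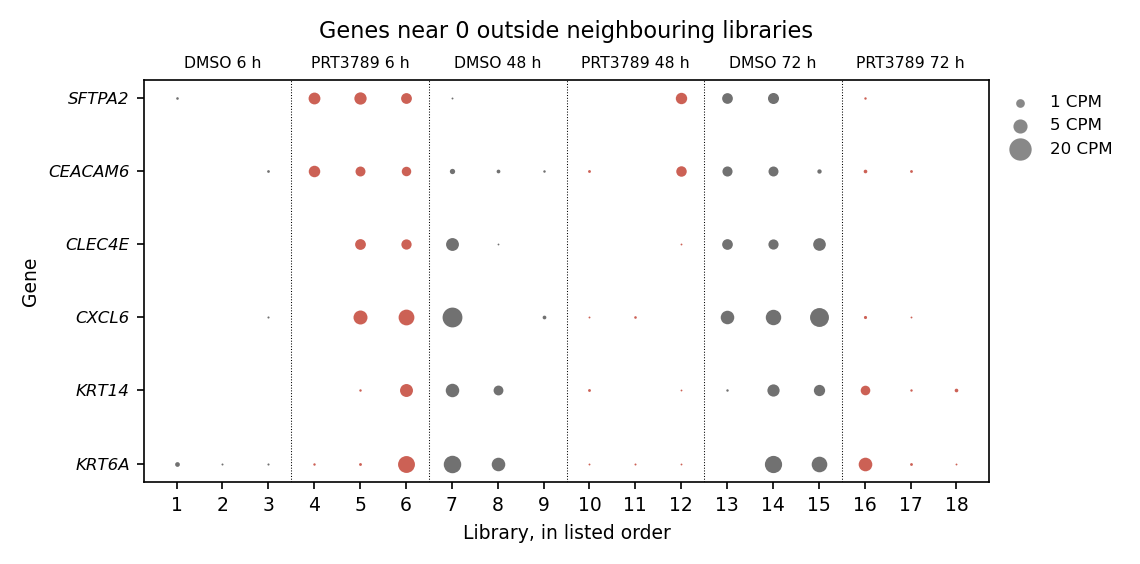
CPM, as dot area, of 6 genes (SFTPA2, CEACAM6, CLEC4E, CXCL6, KRT14 and KRT6A) in the 18 libraries in listed order, DMSO in grey and PRT3789 in red, with dotted lines between groups. Each gene was seen in a few neighbouring libraries and again 8 libraries later.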

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

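Among the tests below, those of the spread and of single libraries were chosen only after the result was seen, and the removal of the length trend was added after the data were seen but its outcome was stated first; the splits of the libraries were planned. A difference between time points in the interaction test brought each of the following results here. The effect of PRT3789 rose between 6 and 48 h for 1438 genes and fell for 1694. The spread of this test was pooled over times, and its share of false calls was not measured. Of the fixed readouts, KRT80 differed by -3.51 and PLAU by -2.63 on the log2 scale. FSTL5 differed by 5.63, GASK1B by 5.04, HNF4G by 2.89, and the ribosomal RNA genes RNA5-8SN1 and RNA5-8SN2, whose copies share reads, by 2.87 each (1.38 without DMSO 6 h replicate 2, 1 of the 13 alternatives of 22 in which the call ended). VTCN1 differed by -5.71, TNNT2 by -5.65, GABRP by -5.55, ALPP by -4.94 and SPRR3 by -4.84. Of the 31 other genes named at 6, 48 or 72 h, 24 differed.

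Of the 36 lists, 10 differed between 6 and 48 h by camera at the preset correlation. The median differences of their members are given as a description and were not tested themselves. The medians were -0.664 for G2/M phase, -0.251 for S phase, -1.16 for mesenchymal genes, -0.337 for integrins and cell adhesion, -0.108 for epithelial junctions and keratins, -0.469 for TGF-beta and BMP targets, -0.245 for cholesterol synthesis, -0.237 for the unfolded protein and integrated stress response, 0.33 for interferon-stimulated genes and 0.2 for antigen presentation. All 10 also differed with the length trend removed. Between 48 and 72 h 14 lists differed. Those lower at 72 h were other chromatin remodellers (-0.298), S phase (-0.172), G2/M phase (-0.129), homologous recombination and Fanconi anaemia (-0.191), YAP/TEAD (-0.167), mesenchymal genes (-0.113), integrins (-0.159), fatty acid metabolism (-0.158) and hypoxia (-0.115). Those higher were cell cycle inhibitors and p53 targets (0.167), antigen presentation (0.104), the unfolded protein and integrated stress response (0.125), oxidative phosphorylation (0.183) and ribosomal proteins (0.198). With the length trend removed, 10 of the 14 still differed; mesenchymal genes, integrins, oxidative phosphorylation and ribosomal proteins did not (adjusted p 0.0569 to 0.254). Of the 72 list tests, G2/M phase between 6 and 48 h was the 1 called with an estimated correlation (adjusted p = 0.00122).

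About 10 times fewer genes were called at 6 h (705) than at 48 h (6853). A larger spread between the 6 h libraries would leave the size of the effects alone, but over 847 genes changed 2-fold at 72 h with a mean of at least 5 CPM the 6 h effect was a median 0.162 of the 48 h effect (quartiles 0.049 and 0.351), against 0.897 for 48 h over 72 h. A single 6 h library apart from its group would lower the count only while it is included, but the most genes called with any 6 h library left out were 1083, without DMSO 6 h replicate 1, and leaving out the others gave 476 to 651. Removal of each library's length trend gave 1076 genes at 6 h, against 7615 at 48 h under the same removal. An effect of PRT3789 that was still building at 6 h may explain the difference, as a hypothesis found in these data; of the 847 genes, 711 (83.9%) already had the direction of 72 h.

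Other splits of the same libraries were counted for each comparison, with list tests adjusted over the 36 lists of a comparison, which calls 10 lists at 6 h in place of 9. For single comparisons the 10 splits are too few for a share under 0.05. At 6 h 2 of the 10 splits gave as many genes (real 705, highest other 5807) and 2 as many lists (10 and 11). At 48 h 1 split gave as many genes (6853, highest other 0) and 9 as many lists (8 and 11), and at 72 h 1 gave as many genes (7069 and 0) and 4 as many lists (10 and 12). The number of list calls at the preset correlation thus did not set the real groups of 48 or 72 h apart from other groupings. This limits what a single list call at that correlation can show. For DMSO between 6 and 48 h the counts were 1, 6059 and 0, and between 48 and 72 h 1, 88 and 1. The change of effect from 6 to 48 h was matched by 7 of 60 splits (3132, highest other 5598). These were drawn from a set in which some splits keep the real groups of 48 h and regroup only those of 6 h. Such splits carry the 48 h effect, so the share does not measure chance, which was not excluded. The change from 48 to 72 h was matched by all 60 of 60 (0, highest other 4281). A count of 0 is matched by any split, so this test could not decide. The 6 h split with 5807 genes, DMSO replicate 1 and PRT3789 replicates 1 and 2 against the other libraries, calls several times the real count and so points to a structure of these samples. In that split 1720 of the 3752 genes of the shortest quartile were lower and 32 higher on the first side, and 1732 of the 3754 longest were higher and 116 lower; it called 3371 genes with the length trend removed.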

How the results depend on the processing

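The fits without pattern genes, without ribosomal RNA genes and with the length trend removed were chosen after the data were seen; the other alternatives were planned. Where a value below differs, the cause was not tested, except that stricter thresholds pass fewer genes by construction. Counts of the comparisons stayed within 1.5 times the given value with DESeq2 size factors, the filter of 1 CPM, limma-voom, blocks over all groups and the fits without pattern or ribosomal RNA genes. At 6 h the higher genes numbered 322 in DESeq2, 396 with the length trend removed, 21 with time points fitted apart, 78 at an adjusted p under 0.01 and 22 at 2-fold; the lower genes numbered 126, 302 and 145 under the last 3. At 2-fold the counts were 714 higher and 1093 lower at 48 h and 864 and 1220 at 72 h. The change of effect from 6 to 48 h gave 755 and 1050 at 0.01 and 395 and 661 at 2-fold; that from 48 to 72 h gave 2 and 1 without a filter, 65 and 38 in DESeq2, 1 and 1 with replicate block within time, and 30 and 18 with the length trend removed. DMSO from 6 to 48 h gave 2090 lower with total counts, 1805 and 2043 at 0.01, and 482 and 260 at 2-fold; DMSO from 48 to 72 h gave 326 and 228 in DESeq2, 156 and 94 with the length trend removed, 18 and 1 at 0.01, and 6 and 3 at 2-fold. List calls numbered 2 of 27 with an estimated correlation; genes called the same way at 6 and 48 h numbered 131 fitted apart and 145 at 2-fold, against 597. With 1 library left out the ranges were 121 to 574 higher and 345 to 509 lower at 6 h, 2662 to 3278 and 2964 to 3263 at 48 h, 3027 to 3114 and 3116 to 3226 at 72 h, 1043 to 1452 and 1432 to 2001 for 48 h against 6 h, 0 to 7 and 0 to 1 for 72 h against 48 h, 2206 to 3791 and 2201 to 3514 in DMSO from 6 to 48 h, 17 to 66 and 2 to 17 in DMSO from 48 to 72 h, 24 to 31 list calls and 412 to 855 shared genes. Of named genes called at 6 h 29 of 78 were called in every setting run on single genes, at 48 h 141 of 151 and at 72 h 136 of 143, and no call reversed. The stricter thresholds were not among these settings. Of the 27 list calls 9 ended without some library, 3 without a filter or fitted apart, and 2 with total counts, the 1 CPM filter, either block or the length trend removed. Replicate numbers did not pair the libraries (2 of 9 correlations over 0.1), and a block over all groups gave 193 higher and 479 lower genes at 6 h. Unrounded counts were not run, as the values were whole. Depth limits genes of few counts, such as SPRR3 at 0.0575 CPM with PRT3789 at 72 h, whose fold change is imprecise.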

Other observations

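The gene groups and tests in this part were chosen after the data were seen. Cornified envelope and kallikrein genes, which mark squamous differentiation, fell together: 13 of 20 measured fell at 48 h and 13 at 72 h, with medians of -1.58 and -1.86 (camera adjusted p 1.15e-10 and 5.55e-10; adjusted p = 0.000555 and 0.00181 with an estimated correlation). KLK6 went from 18.3 ± 0.728 to 0.880 ± 0.392 CPM at 48 h (log2FC -4.35 ± 0.16), the calcium-binding S100A9 from 15.4 ± 1.47 to 1.48 ± 0.355 CPM (-3.36 ± 0.38), and the desmosome-linked periplakin PPL from 320 ± 52.8 to 136 ± 6.64 CPM (-1.23 ± 0.18). The genes found in neighbouring libraries include the kallikrein KLK10, and how many of the falls were such genes was not counted. The list calls at 48 and 72 h held in the fit without such genes. At 6 h 2 of the 20 fell (adjusted p = 0.0348; adjusted p = 0.279 with an estimated correlation). That call ended without PRT3789 6 h replicate 1 (0.106), without a filter (0.228), in DESeq2 (0.0509), with the length trend removed (0.0564) and with the time fitted apart (0.0519).

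Genes of the Hedgehog pathway moved in both directions. At 48 h 5 of 8 rose and 3 fell (adjusted p = 0.0187, and adjusted p = 0.36 with an estimated correlation). Without a filter the camera adjusted p was 0.244, and the list median went from 0.843 to -0.342. GLI1 rose (2.39 ± 0.13), as did its target HHIP (2.24 ± 0.19), the receptor PTCH1 (1.15 ± 0.17), the transducer SMO (0.59 ± 0.09) and the co-receptor CDON (1.09 ± 0.14), while the co-receptors BOC (-2.94 ± 0.68) and GAS1 (-0.91 ± 0.12) and the inhibitor SUFU (-0.39 ± 0.14) fell. At 6 h 3 of the 8 were already higher, GLI1, HHIP and CDON (camera adjusted p = 0.000423, and adjusted p = 0.201 with an estimated correlation). GLI1 was among the largest rises at 6 h and the list was chosen after the data were seen. Its p at 6 h is thus no independent support. Actin and focal adhesion genes fell in 15 of 35 and rose in 5 at 48 h (adjusted p = 0.0041; adjusted p = 0.36 with an estimated correlation). Replication-dependent and linker histones rose in 11 of 35 at 48 h and 13 at 72 h (adjusted p 0.0786 and 0.0181, and adjusted p = 0.745 and 0.597 with an estimated correlation). As RNA was enriched with oligo(dT), these counts cover polyadenylated histone transcripts and do not measure total histone RNA. Receptor tyrosine kinases and their ligands rose in 13 and fell in 10 of 34 at 48 h (adjusted p = 0.812).

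Genes mostly near 0 elsewhere appeared in neighbouring libraries and again 8 libraries later. Of the 26 found in one run, 21 had a mean under 1 CPM in the libraries outside both runs; the other 5 were at up to 145 CPM there (MT-ND4L). Reads split between near-identical gene copies would lower one gene where another rose, but 0 genes were lower in a run. Only runs across a group border could be searched, as a run equal to a group cannot be told from its mean. Treatment with PRT3789 would leave DMSO libraries alike, but the 20 genes found in libraries 5 to 7 were higher in the DMSO libraries of 72 h, 8 places on and not used to find them, than in the 5 DMSO libraries outside the runs (median log2 excess 3.2, lowest 0.372). It would raise the treated libraries of a time alike, but the 6 genes found in libraries 12 to 14 were not higher in the 5 treated libraries of 48 and 72 h outside the runs than in the 4 DMSO libraries there (median -0.696, highest 0.227). Transcripts carried between libraries in the order they are listed may be the source: the 26 genes found in one run had a median log2 excess of 2.96 in the libraries 8 places away, against 2.22 at 9, 1.72 at 7, 0.821 at 10 and 0.229 at 6, where runs 7 and 9 away share 2 of the 3 libraries with the run 8 away. In simulated counts where each time kept its own spread the search gave 193 false genes higher and 235 lower. The real search gave 26 higher and 0 lower, so that simulation does not reproduce these data. How many of the 26 are false was not measured, and no weight is put on their count alone. The excess 8 places away was measured in libraries outside the run a gene was found in. No layout or index was given to test where this arose.

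TAP1, TAP2, PSMB8 and PSMB9, neighbours on chromosome 6, rose together at 48 and 72 h. A general interferon response would raise interferon-stimulated genes as a list. At 72 h 14 of them fell beside 13 that rose, with a median log2FC of 0.0184 (camera adjusted p = 0.807). IRF1 and IFIH1 were among those that rose, so a response limited to some of these genes stays open. Transcripts carried between libraries were predicted to differ between libraries of a group, and the highest TAP1 level was at most 1.06 times the lowest among the treated libraries of a time point. This cannot decide, as SFTPA2 filled the PRT3789 libraries of 6 h about evenly (4.77, 5.27 and 3.73 CPM). TAP1 did not repeat 8 libraries apart. It was at 140.4 and 135.5 CPM in DMSO 48 h replicates 2 and 3, which lie 8 places before PRT3789 72 h replicates 1 and 2 (1585 and 1497 CPM). A change along the whole stretch around TAP1 would raise its neighbours about as much, but the 18 other genes within 500 kb with a mean of at least 5 CPM had a median log2FC of 0.06 at 48 h (quartiles -0.12 and 0.27) and 0.1 at 72 h (-0.01 and 0.19), against 1.33 and 1.6 for the least raised of the 4. Of all 27 tested neighbours 8 rose and 3 fell at 48 h, where 21.2% of all tested genes rose, and 6 rose and 2 fell at 72 h. HLA-DRB1 (0.94 and 1.99) and TAPBP (0.82 at 48 h) were among those that rose. PSMB8-AS1, which overlaps TAP1 in position and had a mean of 1.66 CPM, was at 1.06 and 1.96. A change shared with some neighbours therefore stays open. The rise itself was seen with PRT3789 against DMSO of the same time. Whether PRT3789 acts on this group of genes directly or through other genes was not tested and stays open.

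The counts of DMSO 48 h replicate 3 add up to 27000000, a round number.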
